A study of Mus musculus with 33 samples.

How the data were processed

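Total RNA had been isolated with Trizol and RNeasy columns with DNase I, and biotin-labelled cRNA was made with the Ambion MessageAmp kit, per the labels. The authors deposited probe intensities exported from BeadStudio 3.1.3, per the submitters' processing notes, and the deposited intensities are labelled as not normalized. The 45281 probes ran from 14.5 to 71976 and array medians differ, so no normalization between arrays was seen. Beside each intensity the authors deposited a detection p-value, made in BeadStudio by comparing a probe with negative control beads, which takes 936 steps here. The authors also deposited log2 values whose columns share 1 distribution and rank probes exactly as the intensities do, so they were quantile normalized before deposit. They were used only as an alternative, and which arrays the authors normalized together is not stated.

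Gene symbols came from the probe annotation and were updated through the Entrez identifier, for 34807 probes. Of the 45281 probes 34885 carried 1 symbol, 18 several and 10378 none. Intensities were corrected with the normexp model of the neqc function of limma, with negative control statistics inferred from the detection p-values, then offset by 16, quantile normalized and taken to log2. A probe was kept if its detection p was under 0.01 on at least 3 of the 33 arrays, which left 17243 probes. The brightest probe over all arrays stood for each gene, which left 9613 genes of 19057 with a probe.

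A linear model with 1 coefficient for each of the 11 groups was fitted with limma, with 22 residual and 4.133 prior degrees of freedom. Moderated t and F tests were adjusted by the Benjamini-Hochberg method over all 9613 genes, and genes under 0.05 passed. High-fat minus normal diet was taken at each of 5 weeks and as their mean. Further tests were weeks 20 and 24 minus weeks 2 and 4, any diet by week interaction, week 24 minus week 0 on normal diet, and any change over the normal diet weeks. Of 29 gene lists, with 651 genes fixed and 481 measured, 28 had at least 5 measured genes and were tested with camera at a preset correlation of 0.01 and again with an estimated one. The list of red blood cell genes had 3 measured genes and was left out. The analysis choices were fixed before the data were examined, apart from those named here as added later.

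Genes were named by a fixed rule. For the diet average these were the 10 largest rises and falls that passed with 1 sign at all 5 weeks. For each week they were the 5 largest each way that passed and whose 3 high-fat arrays did not overlap the 3 normal diet arrays, which chance gives in 10% of cases. For late against early they were the 5 largest each way, for week 24 against week 0 the 10 largest each way, and for each F test the 5 smallest p. To these came 15 genes of brown fat and lipid metabolism fixed in advance, and up to 4 members of a list with the smallest p. A gene with no array detected in 1 of 2 groups was given as at least so many fold. Its floor was the mean over that group's arrays of the higher of the lowest detected signal and the probe's own.

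Alternatives were no background correction, a median shift in place of quantile normalization, the authors' values, no detection filter, detection on all 3 arrays of a group, the mean of a gene's probes, a replicate block, array weights, and a trended robust prior. Others were the 6 arrays of 1 week alone, the skeletal muscle or the lymphocyte mean as a covariate, each of 33 arrays left out, and the estimated list correlation. Fits without week 8 or week 24, and week 20 in place of week 24, were added after the data were seen. In simulated arrays with known changes, 68%, 96%, 100% and 100% of genes changed by 0.3, 0.6, 1 and 2 log2 units were recovered for the diet average, with 5.21% of calls false. For single weeks these shares were 18%, 56%, 96% and 100% at week 8, with 7.53% of calls false, and 18%, 68%, 92% and 100% at week 24, with 4.14% false. The simulated noise was independent between genes and had the same spread in all groups, and each change was equal at every week. These shares are therefore not error rates of the real calls, where arrays differ in quality. R 4.3.3, limma 3.58.1, the data.table package (version 1.17.8) and matplotlib 3.10.9 were used.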

Results

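Interscapular brown fat, the heat-producing fat depot between the shoulder blades, was profiled in C57BL/6J mice on Illumina mouse bead arrays, which read each transcript as the brightness of a probe. Animals ate an AIN-76 semi-purified diet (normal diet) or the same diet with 39.2 kcal% fat, given as 20% fat and 1% cholesterol (high-fat diet). They lived singly at 24 °C with 12-hour light periods. Normal diet groups were taken at weeks 0, 2, 4, 8, 20 and 24 and high-fat groups at weeks 2, 4, 8, 20 and 24, which gave 11 groups of 3 arrays, 33 arrays in all. The labels list an age of 7 weeks for every sample and number the replicates without saying that they were separate animals, so p-values measure the spread between these samples. Median signals ran from 129 to 183 per array, and 29.5% to 33.7% of probes were detected. Arrays of 1 group correlated across genes at r of 0.977 to 0.996, and the number of arrays limits the precision. The series title names the effect of a high-fat diet on brown fat development as its subject, so diet was compared within each week and weeks were compared within normal diet.

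The arrays of week 24 stood apart from the others whatever the diet. On the first principal component, which held 35.9% of the variance, normal diet arrays of week 24 scored 34.4 ± 1.54 (SD, n = 3) and high-fat arrays of week 24 scored 46.0 ± 0.878 (SD, n = 3), while the means of the other groups lay between -15.1 and 2.70. The diet difference of week 24 was taken within that week's own arrays.

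**Figure D1:**
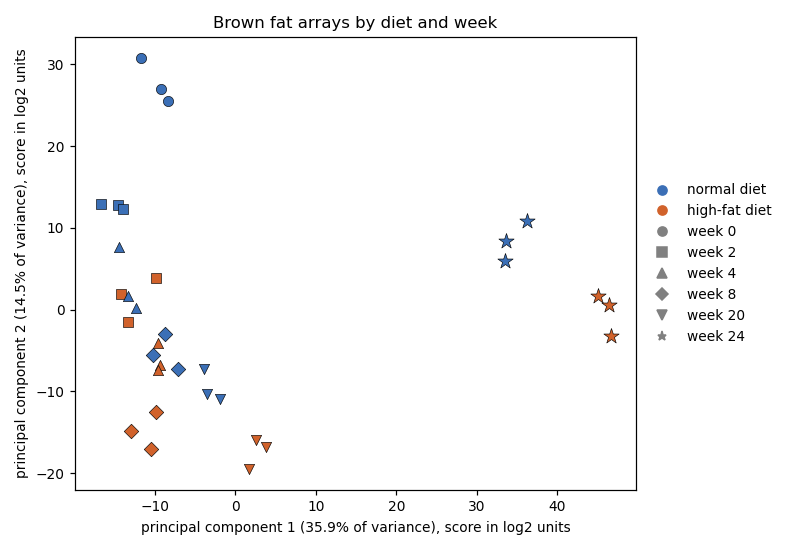
Scores of the 33 arrays on the first and second principal components of the log2 values of 9613 genes, with colour for diet and symbol for week. The 6 arrays of week 24 lie at the right, with mean scores of 34.4 on normal and 46.0 on high-fat diet on the first component, and no other group mean exceeds 2.70.

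High-fat feeding raised Epdr1, which encodes an ependymin-related secreted protein, by 1.57 log2 units (SE 0.10, probe ILMN_1225494, adjusted p = 4e-11), as the mean of the 5 within-week differences. It passed at each of the 5 weeks. Pon1, a lipoprotein-associated paraoxonase, rose by 1.28 (SE 0.094, adjusted p = 2.68e-10). Hcn2, a pacemaker ion channel, rose by 1.29 (SE 0.12, adjusted p = 6.64e-09). The calcium release channel gene Ryr2 rose by 1.13 (SE 0.094), the taurine and GABA transporter gene Slc6a13 by 1.16 (SE 0.13), and the imprinted adipose gene Nnat by 1.07 (SE 0.13). The nicotinamide methyltransferase gene Nnmt rose by 1.01 (SE 0.089). Ido1, which encodes a tryptophan-degrading enzyme induced by interferon, rose by 1.01 (SE 0.12), the kinase gene Sgk2 by 0.99 (SE 0.12) and the transcription factor gene Sox9 by 0.97 (SE 0.10). The largest falls among genes with 1 sign at all 5 weeks were in Apoc3, an apolipoprotein of triglyceride-rich particles, at -0.997 (SE 0.098, adjusted p = 2.72e-08), and Tmem184a at -0.99 (SE 0.075, adjusted p = 3.92e-10). Sorcs2 changed by -0.95 (SE 0.092), Prune2 by -0.89 (SE 0.075), the squalene epoxidase gene Sqle by -0.82 (SE 0.061), and the scaffold gene Mapk8ip1 by -0.81 (SE 0.066). Gstp3 changed by -0.77 (SE 0.079), the acute-phase gene Orm2 by -0.75 (SE 0.067), the parathyroid hormone receptor gene Pth1r by -0.71 (SE 0.055) and the melanocortin receptor gene Mc5r by -0.71 (SE 0.092). Ryr2, Ido1 and Mc5r were detected on 10, 9 and 6 of the 33 arrays, so their fitted values rest largely on signals below detection.

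Genes that make lipid fell together. In the cholesterol synthesis and uptake list 13 of 17 measured genes fell and 0 rose (13 fell when adjusted over the list alone), with a mean of -0.35 (camera adjusted p = 8.85e-11). Sqle led, followed by the mevalonate pathway genes Pmvk (-0.62, SE 0.059) and Fdps (-0.53, SE 0.047) and the lanosterol demethylase gene Cyp51 (-0.46, SE 0.047). In the fatty acid synthesis list 12 of 20 genes fell and 0 rose (12 adjusted over the list alone), with a mean of -0.29 (camera adjusted p = 6.87e-11). Among them were the elongases Elovl6 (-0.61, SE 0.050) and Elovl5 (-0.51, SE 0.044), the citrate carrier Slc25a1 (-0.61, SE 0.057) and the acetyl-CoA synthetase gene Acss2 (-0.52, SE 0.056). Fasn, fatty acid synthase, changed by -0.62 (SE 0.074, adjusted p = 5.93e-07), while the desaturase Scd1 did not pass (-0.05, SE 0.028, adjusted p = 0.155). In the fatty acid oxidation list 14 of 30 genes rose and 3 fell (16 and 3 adjusted over the list alone). Its mean was 0.10 (camera adjusted p = 0.00199, adjusted p = 0.163 with an estimated correlation), and it was -0.02 with adjusted p = 0.25 when arrays were aligned by a median shift. Within it the fatty acid binding protein gene Fabp3 rose by 0.64 (SE 0.039), Decr1 by 0.25 (SE 0.050) and Acads by 0.20 (SE 0.037), whereas the acyl-CoA thioesterase gene Acot1 changed by -0.44 (SE 0.073).

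Immune, vascular and matrix genes were higher on high-fat diet. In the macrophage list 19 of 23 genes rose and 0 fell (21 adjusted over the list alone), with a mean of 0.44 (camera adjusted p = 4.23e-13). They included the chemokine gene Ccl9 (0.71, SE 0.067), the mannose receptor gene Mrc1 (0.58, SE 0.063), the macrophage elastase gene Mmp12 (0.53, SE 0.064) and the complement gene C1qa (0.44, SE 0.057). All 7 measured MHC class II genes rose (7 adjusted over the list alone), with a mean of 0.41 (camera adjusted p = 8.79e-05, adjusted p = 0.163 with an estimated correlation). Among them were H2-Ab1 (0.48, SE 0.090) and Cd74 (0.47, SE 0.088). In the interferon response list 13 of 20 genes rose and 0 fell (15 adjusted over the list alone), with a mean of 0.35 (camera adjusted p = 1.61e-07, adjusted p = 0.0772 with an estimated correlation). They included the GTPase gene Gbp3 (0.70, SE 0.11) and the immunoproteasome gene Psmb8 (0.53, SE 0.091). Endothelial genes rose in 14 of 19 cases (14 adjusted over the list alone; mean 0.20, camera adjusted p = 1.94e-07), with Icam2 at 0.44 (SE 0.057) and Mmrn2 at 0.26 (SE 0.040). Extracellular matrix genes rose in 15 of 24 cases (17 rose and 1 fell adjusted over the list alone; mean 0.21, camera adjusted p = 2.65e-07), with Fn1 at 0.52 (SE 0.086) and Bgn at 0.38 (SE 0.047). Cell cycle genes rose in 13 of 19 cases (14 adjusted over the list alone; mean 0.27, camera adjusted p = 2.18e-06), with Prc1 at 0.68 (SE 0.095) and Tk1 at 0.49 (SE 0.065). In fits without week 24, chosen after seeing the data, the matrix and cell cycle lists no longer passed (means 0.07 and 0.09, adjusted p = 0.0602 and 0.0928), and the mean of the macrophages list was 0.16.

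In the brown fat thermogenesis list 5 of 24 genes rose and 2 fell (5 and 2 adjusted over the list alone; mean 0.04, camera adjusted p = 0.50). Ucp1, the uncoupling protein that makes heat, differed by 0.04 (SE 0.048, adjusted p = 0.557) and by -0.12 when arrays were aligned by a median shift. Its log2 values of 15.2 to 15.9 per group were near the top of the scale, as were those of Cidea (15.6 to 15.91), Lpl (15.79 to 15.93) and Scd1 (15.88 to 16.02), where differences are hard to see. Cidea (-0.04, SE 0.026, adjusted p = 0.275), Ppargc1a (0.22, SE 0.14, adjusted p = 0.269) and Elovl3 (-0.18, SE 0.071, adjusted p = 0.0593) did not pass. The carnitine palmitoyltransferase gene Cpt1b (0.20, SE 0.045, adjusted p = 0.00145), the hormone gene Fgf21 (0.31, SE 0.083, adjusted p = 0.0058) and Pdk4 (0.18, SE 0.067, adjusted p = 0.0466) rose. The call of Pdk4 was lost in 31 of 46 other settings, and with the median shift Pdk4 stood at 0.04 (adjusted p = 0.679) and Cpt1b at 0.06 (adjusted p = 0.458). Fgf21 did not pass without week 24 (adjusted p = 0.113), and its lowest value over the 46 settings was 0.13. Dio2 was detected on at most 2 arrays and was not tested. White adipocyte markers rose in 8 of 12 cases and fell in 1 (8 and 1 adjusted over the list alone; mean 0.35, camera adjusted p = 1.97e-04). They were led by Nnat, the leptin gene Lep (0.81, SE 0.13, adjusted p = 3.27e-05), the synuclein gene Sncg (0.76, SE 0.071) and Dpt (0.39, SE 0.065). Adipoq (0.10, SE 0.037, adjusted p = 0.0568) and Lpl (0.02, SE 0.032, adjusted p = 0.693) did not pass, and their values were -0.05 and -0.09 with the median shift. Adipoq passed or changed direction in 11 of 46 other settings, and Elovl3 passed in 12. In the creatine and calcium cycling list 3 of 8 genes rose and 0 fell (3 adjusted over the list alone; mean 0.32, camera adjusted p = 0.0127, adjusted p = 0.0616 with an estimated correlation). These were Ryr2, the brain-type creatine kinase gene Ckb (0.57, SE 0.053) and the calcium pump gene Atp2a2 (0.24, SE 0.042). The skeletal muscle markers averaged 0.26 with 0 of 20 past the threshold (0 adjusted over the list alone; camera adjusted p = 0.0992).

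Across all genes, 2602 of 9613 differed between diets on average, 1480 higher and 1122 lower, by limma with Benjamini-Hochberg adjustment. Only 8 rose and 1 fell by more than 2-fold. Of the 2602 genes 1574 had 1 sign at all 5 weeks, and 18 genes passed at each of the 5 weeks on their own. Without week 24 the count was 1470. With a median shift 3094 genes passed and 25.3% of them were higher, against 56.9% here, so the balance of rises and falls turned with the scaling.

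**Figure D2:**
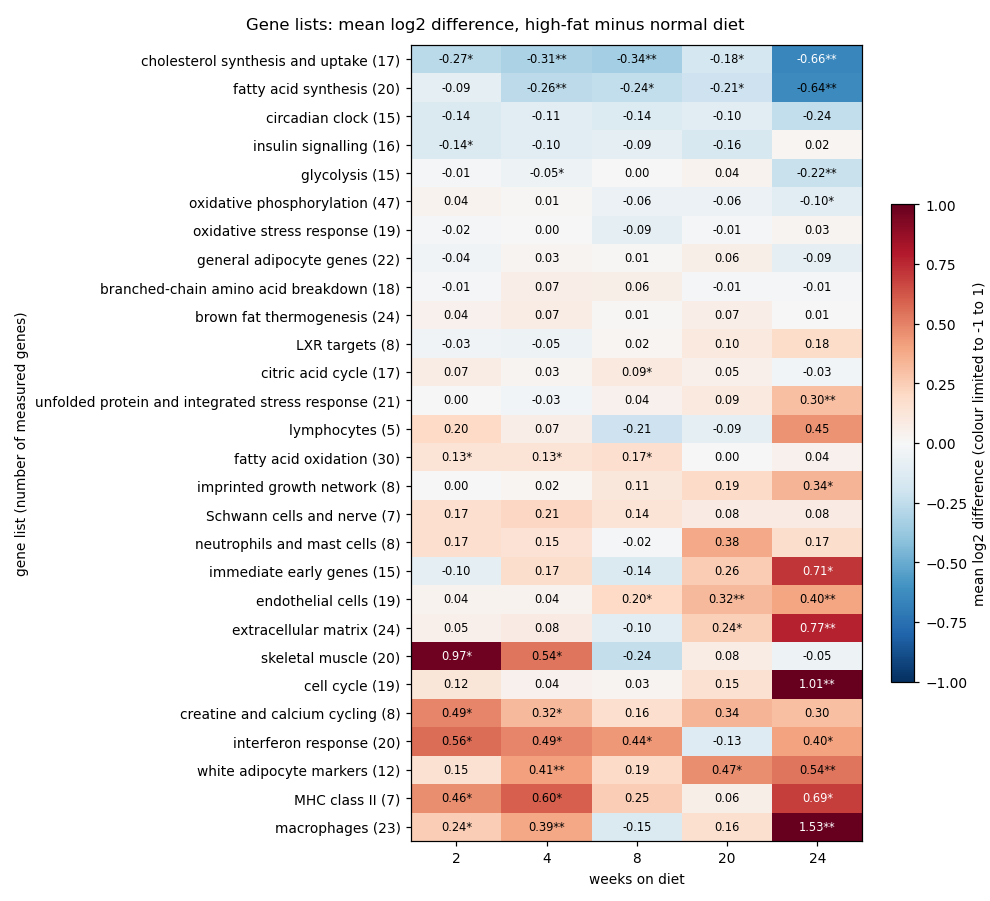
Mean log2 difference, high-fat minus normal diet, of each of the 28 tested gene lists (lines, with the number of measured genes) at weeks 2, 4, 8, 20 and 24 (columns), 3 arrays per diet and week. One asterisk marks a camera call with the preset correlation and a double asterisk a call that also held with an estimated correlation. Cholesterol genes lie below 0 at each week, from -0.18 at week 20 to -0.66 at week 24, and macrophage genes reach 1.53 at week 24.

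At week 2, interferon-induced GTPase genes were among the strongest risers. Igtp stood at 11.19 ± 0.12 on high-fat and 9.42 ± 0.18 on normal diet (log2, SD, n = 3 each), a rise of 1.77 (SE 0.35, adjusted p = 0.00674). Irgm2 rose by 1.51 (SE 0.25, adjusted p = 0.00137) and Gbp2 by 1.44 (SE 0.26, adjusted p = 0.00275). Epdr1 rose by 1.70 (SE 0.23) and the sodium channel subunit gene Scn4b by 1.55 (SE 0.32), whose other probe moved the opposite way. Fkbp5, a glucocorticoid-induced cochaperone gene, changed by -1.84 (SE 0.44, adjusted p = 0.0267), the cytochrome gene Cyp2b23 by -1.56 (SE 0.41, adjusted p = 0.0477) and the glutathione transferase gene Gsta3 by -1.07 (SE 0.15, adjusted p = 2.99e-04). Mc5r and Tmem184a were below detection on all 3 high-fat arrays and at least 1.74-fold and 1.83-fold lower there (adjusted p = 2.9e-05 for both).

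Among the lists at week 2, interferon response genes rose in 6 of 20 cases and fell in 0 (9 adjusted over the list alone; mean 0.56, camera adjusted p = 3.51e-10, adjusted p = 0.0785 with an estimated correlation). They included Gbp3 (1.32, SE 0.24) and Psmb9 (1.04, SE 0.24). Cholesterol genes fell in 3 of 17 cases (3 adjusted over the list alone; mean -0.27, camera adjusted p = 1.88e-05, adjusted p = 0.0513 with an estimated correlation). Sqle stood at -0.81 (SE 0.14), Hsd17b7 at -0.56 (SE 0.13) and Cyp51 at -0.47 (SE 0.11). In the insulin signalling list 2 of 16 genes fell, Igf1 at -0.70 (SE 0.15) and Igfbp4 at -0.53 (SE 0.090), with 3 adjusted over the list alone (mean -0.14, camera adjusted p = 0.0436, adjusted p = 0.0957 with an estimated correlation). The insulin signalling call was lost in 11 of 47 other settings, with a highest adjusted p of 0.213. Fatty acid oxidation genes averaged 0.13 with 1 riser, Fabp3 at 0.59 (SE 0.087) (1 adjusted over the list alone; camera adjusted p = 0.00149, adjusted p = 0.252 with an estimated correlation). Macrophage genes averaged 0.24 with 1 of 23 past the threshold (4 adjusted over the list alone; camera adjusted p = 7.23e-04, adjusted p = 0.252 with an estimated correlation). MHC class II genes averaged 0.46 with 0 of 7 (5 adjusted over the list alone; camera adjusted p = 4.89e-04, adjusted p = 0.315 with an estimated correlation). Skeletal muscle markers also averaged higher, by 0.97, with 0 of 20 past the threshold (0 adjusted over the list alone; camera adjusted p = 3.79e-08, adjusted p = 0.446 with an estimated correlation). The creatine and calcium list, which shares Atp2a1 with the muscle list, averaged 0.49 with Ryr2 past it (4 adjusted over the list alone; camera adjusted p = 0.00144, adjusted p = 0.0513 with an estimated correlation). Ucp1 (-0.06, SE 0.11, adjusted p = 0.863), Lep (-0.05, SE 0.29, adjusted p = 0.965) and Fasn (-0.17, SE 0.17, adjusted p = 0.724) did not differ detectably. In all, 183 genes passed, 109 higher and 74 lower. That count was 90 with the muscle mean as a covariate, which also ended the calls of Fkbp5 and Cyp2b23. The call of Cyp2b23 was lost in 31 of 47 other settings, and Scn4b was 0.62 (adjusted p = 0.122) as the mean of its probes. The muscle list stood at 9.33, 9.73 and 10.56 on high-fat replicates 1, 2 and 3. Its mean difference ran from 0.63 to 1.24 over 46 other settings.

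At week 4, Pon1 stood at 9.88 ± 0.24 on high-fat and 8.38 ± 0.19 on normal diet (log2, SD, n = 3 each), a rise of 1.499 (SE 0.21, adjusted p = 2.46e-04). Sgk2 rose by 1.38 (SE 0.27, adjusted p = 0.00663) and Epdr1 by 1.34 (SE 0.23, adjusted p = 0.0022). Ido1 and Nnat were below detection on normal diet and at least 1.66-fold and 1.95-fold higher on high-fat diet (adjusted p = 0.00167 and 0.00463). Ido1 was detected on 2 of the 3 high-fat arrays. Prune2 changed by -1.40 (SE 0.17, adjusted p = 5.15e-05), the phosphatase gene Dusp4 by -1.33 (SE 0.24, adjusted p = 0.00374), Lctl by -1.12 (SE 0.18, adjusted p = 0.00149) and Apoc3 by -1.08 (SE 0.22, adjusted p = 0.00897). Tmem184a was below detection on high-fat diet and at least 1.13-fold lower there (adjusted p = 0.00149).

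The lipid synthesis lists fell at week 4. In the cholesterol list 4 of 17 genes fell (6 adjusted over the list alone; mean -0.31, camera adjusted p = 5.94e-08), and in the fatty acid synthesis list 4 of 20 (8 adjusted over the list alone; mean -0.26, camera adjusted p = 7.87e-09). Fdps stood at -0.63 (SE 0.11), Slc25a1 at -0.64 (SE 0.13), the malic enzyme gene Me1 at -0.63 (SE 0.16) and Elovl5 at -0.56 (SE 0.099). Macrophage genes averaged 0.39 with 1 riser, C1qa at 0.65 (SE 0.13) (13 adjusted over the list alone; camera adjusted p = 7.4e-10). White adipocyte markers averaged 0.41 with 3 of 12 risers, Nnat, Sncg (0.77, SE 0.16) and Dpt (0.64, SE 0.15) (4 adjusted over the list alone; camera adjusted p = 5.23e-05). Interferon genes averaged 0.49 with 3 risers, Igtp (1.40, SE 0.35), Gbp3 (1.02, SE 0.24) and Psmb8 (0.83, SE 0.20) (11 adjusted over the list alone; camera adjusted p = 7.4e-10, adjusted p = 0.0579 with an estimated correlation). MHC class II genes averaged 0.60 with 0 of 7 past the threshold (5 adjusted over the list alone; camera adjusted p = 4.79e-07, adjusted p = 0.102 with an estimated correlation). Fatty acid oxidation genes averaged 0.13 with Fabp3 at 0.66 (SE 0.087) the 1 riser (1 adjusted over the list alone; camera adjusted p = 1.55e-04, adjusted p = 0.105 with an estimated correlation). Glycolysis genes averaged -0.05 with Aldoa the 1 that fell, at -0.32 (SE 0.075) (4 adjusted over the list alone; camera adjusted p = 0.0429, adjusted p = 0.23 with an estimated correlation). Skeletal muscle markers averaged 0.54 with 0 of 20 past the threshold (0 adjusted over the list alone; camera adjusted p = 0.00162, adjusted p = 0.668 with an estimated correlation). The skeletal muscle list, changed by diet at week 4, averaged 0.11 (adjusted p = 0.716) without normal diet replicate 3. The creatine and calcium list averaged 0.32 with Atp2a2 past it at 0.43 (SE 0.093) (3 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0172, adjusted p = 0.0881 with an estimated correlation). The call of the glycolysis list was lost in 12 of 47 other settings, among them the replicate block (adjusted p = 0.0513). Fasn at -0.64 (SE 0.17, adjusted p = 0.0533), Lep at 0.78 (SE 0.29, adjusted p = 0.211) and Ucp1 at 0.06 (SE 0.11, adjusted p = 0.897) did not pass. In all, 115 genes passed, 70 higher and 45 lower. The count was 197 without background correction and 62 with a median shift. Fitted on the 6 arrays of the week alone, 1 gene passed. That gene was Epdr1 (adjusted p = 0.022), so the other genes named for this week lost their calls there. The adjusted p was 0.0552 for Pon1 and Sgk2, 0.0615 for Prune2, 0.0878 for Dusp4 and 0.0592 for Lctl. It was 0.167 for Ido1, 0.103 for Nnat and 0.0966 for Tmem184a.

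At week 8, the MHC class I gene H2-Q6 stood at 8.18 ± 0.18 on high-fat and 6.84 ± 0.13 on normal diet (log2, SD, n = 3 each), a rise of 1.35 (SE 0.23, adjusted p = 0.00565). It belongs to a family of near-identical genes that a probe may not tell apart. Epdr1 rose by 1.16 (SE 0.23, adjusted p = 0.00973) and the interferon-induced GTPase gene Ifi47 by 1.16 (SE 0.30, adjusted p = 0.0394). Ido1 and Ryr2 were below detection on normal diet and at least 1.72-fold and 1.29-fold higher on high-fat diet (adjusted p = 0.0124 and 0.00568). Ryr2 was detected on 2 of the 3 high-fat arrays. The orphan nuclear receptor gene Nr4a2 changed by -1.37 (SE 0.27, adjusted p = 0.012), the glycogen-targeting gene Ppp1r3g by -1.23 (SE 0.29, adjusted p = 0.0249) and Irf4, an interferon regulatory factor family gene, by -1.13 (SE 0.25, adjusted p = 0.0182). Lst1 and Dhx9 were below detection on high-fat diet and at least 1.59-fold and 1.5-fold lower there (adjusted p = 0.0215 and 0.0169). The calls of Ifi47 and Ppp1r3g were lost in 7 and 6 of 46 other settings (highest adjusted p = 0.366 and 0.293).

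Cholesterol genes fell in 4 of 17 cases at week 8 (6 adjusted over the list alone; mean -0.34, camera adjusted p = 1.17e-06). Sqle stood at -0.84 (SE 0.14), Pmvk at -0.65 (SE 0.13) and Lss at -0.55 (SE 0.13). Fatty acid synthesis genes fell in 6 of 20 cases (8 adjusted over the list alone; mean -0.24, camera adjusted p = 6.5e-05, adjusted p = 0.148 with an estimated correlation), with the citrate lyase gene Acly at -0.49 (SE 0.10). Interferon genes averaged 0.44 with 2 risers, Gbp3 (1.11, SE 0.24) and the RNA sensor gene Ddx58 (0.67, SE 0.16) (7 adjusted over the list alone; camera adjusted p = 1.04e-06, adjusted p = 0.157 with an estimated correlation). Macrophage genes did not pass at this week (mean -0.15, camera adjusted p = 0.26). Of its genes 1 of 23 fell, Tyrobp at -0.93 (SE 0.24) (2 adjusted over the list alone). Fatty acid oxidation genes averaged 0.17 with 2 risers, Hadh (0.68, SE 0.16) and Fabp3 (0.46, SE 0.087) (5 adjusted over the list alone; camera adjusted p = 1.84e-05, adjusted p = 0.146 with an estimated correlation). Endothelial genes averaged 0.20 with 0 of 19 past the threshold (3 adjusted over the list alone; camera adjusted p = 5.09e-05, adjusted p = 0.146 with an estimated correlation). Citric acid cycle genes averaged 0.09 with 0 of 17 (0 rose adjusted over the list alone; camera adjusted p = 0.022, adjusted p = 0.44 with an estimated correlation). Without high-fat replicate 1 the citric acid cycle mean was 0.006489 (adjusted p = 0.862). In the insulin signalling list, which did not pass (mean -0.09, camera adjusted p = 0.46), Igf1 was the 1 gene that fell, at -0.85 (SE 0.15). Ucp1 (-0.04, SE 0.11, adjusted p = 0.89) and Lep (0.45, SE 0.29, adjusted p = 0.428) did not pass. In all, 202 genes passed, 89 higher (44.1%) and 113 lower. The high-fat arrays of week 8 had a mean signal of 527.5 ± 62.6 against 732 ± 25.2 on normal diet (SD, n = 3 each). Aligned by a median shift, the median of all genes was -0.31, 3727 genes passed with 0.912% of them higher. The means of the oxidation, endothelial and citric acid cycle lists were then -0.16, -0.15 and -0.27, the latter 2 without a call. Fitted on the 6 arrays of the week alone, 1 gene passed, with 783 at an unadjusted p under 0.05.

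At week 20, Epdr1 stood at 8.71 ± 0.33 on high-fat and 6.52 ± 0.30 on normal diet (log2, SD, n = 3 each), a rise of 2.19 (SE 0.23, adjusted p = 4.2e-06). Slc6a13 rose by 1.81 (SE 0.30, adjusted p = 7.02e-04), Ryr2 by 1.70 (SE 0.21), Pon1 by 1.67 (SE 0.21) and Nnmt by 1.60 (SE 0.20), the latter 3 with an adjusted p = 2.53e-05 each. Lep rose by 1.49 (SE 0.29, adjusted p = 0.00315) and Fgf21 by 0.70 (SE 0.18, adjusted p = 0.0283). The falls included FOXO-regulated Depp1 at -1.99 (SE 0.53, adjusted p = 0.0301), the MYC family gene Mycl at -1.75 (SE 0.35, adjusted p = 0.00462), the PI3K inhibitor gene Pik3ip1 at -1.53 (SE 0.30, adjusted p = 0.00344), the GLUT4 trafficking gene Tbc1d4 at -1.34 (SE 0.31, adjusted p = 0.0128) and Irf4 at -1.15 (SE 0.25, adjusted p = 0.00821). Fasn changed by -0.70 (SE 0.17, adjusted p = 0.0134), while Ucp1 (0.10, SE 0.11, adjusted p = 0.673) and Elovl3 (-0.23, SE 0.16, adjusted p = 0.462) did not pass.

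Endothelial genes rose in 8 of 19 cases at week 20 (12 adjusted over the list alone; mean 0.32, camera adjusted p = 1.34e-08). Icam2 stood at 0.57 (SE 0.13), Sox18 at 0.49 (SE 0.10), Mmrn2 at 0.40 (SE 0.090) and Egfl7 at 0.36 (SE 0.078). Extracellular matrix genes rose in 4 of 24 cases (9 adjusted over the list alone; mean 0.24, camera adjusted p = 1.3e-04, adjusted p = 0.128 with an estimated correlation). Among them were Nid1 (0.51, SE 0.11) and Bgn (0.39, SE 0.10). White adipocyte markers rose in 3 of 12 cases (7 adjusted over the list alone; mean 0.47, camera adjusted p = 7.57e-04, adjusted p = 0.0686 with an estimated correlation). These were Lep, Npr3 (0.71, SE 0.16) and Sncg (0.65, SE 0.16). Fatty acid synthesis genes fell in 5 of 20 cases (6 adjusted over the list alone; mean -0.21, camera adjusted p = 1.43e-05, adjusted p = 0.104 with an estimated correlation). Elovl6 stood at -0.65 (SE 0.11) and Aacs at -0.54 (SE 0.093). Cholesterol genes fell in 2 of 17 (6 adjusted over the list alone; mean -0.18, camera adjusted p = 0.00419, adjusted p = 0.144 with an estimated correlation). The interferon list did not pass at week 20 (mean -0.13, camera adjusted p = 0.112), nor did the macrophage list (mean 0.16, camera adjusted p = 0.102), although Mrc1 rose by 0.62 (SE 0.14) and C1qa by 0.44 (SE 0.13). In all, 449 genes passed, 293 higher (65.3%) and 156 lower, and with a median shift 375 passed with 14.1% higher. The high-fat arrays of week 20 had a mean signal of 607.8 ± 56.8 against 655.9 ± 28.1 on normal diet (SD, n = 3 each). The call of Irf4 was lost without background correction (-0.52). The call of Depp1 was lost in 7 of 47 other settings (highest adjusted p = 0.125, without 1 high-fat array).

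At week 24, Gpnmb, a glycoprotein gene of phagocytes, stood at 12.4 ± 0.089 on high-fat and 9.19 ± 0.42 on normal diet (log2, SD, n = 3 each), a rise of 3.21 (SE 0.31, adjusted p = 1.34e-08). The lipid-sensing receptor gene Trem2 rose by 3.05 (SE 0.21, adjusted p = 7.76e-11), the galectin gene Lgals3 by 2.95 (SE 0.24, adjusted p = 7.66e-10) and Ccl9 by 2.62 (SE 0.15, adjusted p = 1.8e-12). The chemokine gene Ccl7, below detection on normal diet, was at least 6.91-fold higher (adjusted p = 5.83e-11). Sorcs2 changed by -2.08 (SE 0.21, adjusted p = 2.81e-08), Prune2 by -1.67 (SE 0.17, adjusted p = 3.51e-08) and Apoc3 by -1.64 (SE 0.22, adjusted p = 2.88e-06). Dmrtc1a and Tlcd3b were below detection on high-fat diet and at least 3.38-fold and 2.45-fold lower there (adjusted p = 8e-07 and 1.33e-04). Lep rose by 1.39 (SE 0.29, adjusted p = 8.15e-04), Fgf21 by 0.62 (SE 0.18, adjusted p = 0.0178) and Cpt1b by 0.30 (SE 0.10, adjusted p = 0.0309). Fasn changed by -1.16 (SE 0.17, adjusted p = 8.47e-06) and the brown fat elongase gene Elovl3 by -0.82 (SE 0.16, adjusted p = 4.45e-04), while Ucp1 did not pass (0.16, SE 0.11, adjusted p = 0.327).

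Macrophage genes rose in 21 of 23 cases at week 24 and fell in 0 (23 adjusted over the list alone; mean 1.53, camera adjusted p = 4.3e-25). Extracellular matrix genes rose in 22 of 24 cases (22 adjusted over the list alone; mean 0.77, camera adjusted p = 1.59e-16). They included the metalloproteinase inhibitor gene Timp1, below detection on normal diet and at least 2.74-fold higher, the collagen genes Col5a1 (1.32, SE 0.13) and Col1a1 (1.30, SE 0.14), and Bgn (1.03, SE 0.10). Cell cycle genes rose in 15 of 19 cases (15 adjusted over the list alone; mean 1.01, camera adjusted p = 2.08e-13), with Prc1 at 2.31 (SE 0.21). Endothelial genes rose in 12 of 19 cases (14 adjusted over the list alone; mean 0.40, camera adjusted p = 7.05e-07). White adipocyte markers rose in 7 of 12 with 1 fall (8 and 1 adjusted over the list alone; mean 0.54, camera adjusted p = 0.00252), Cyp2e1 at -1.24 (SE 0.22). Fatty acid synthesis genes fell in 13 of 20 cases (16 adjusted over the list alone; mean -0.64, camera adjusted p = 1.37e-13). Elovl6 stood at -1.18 (SE 0.11), Slc25a1 at -1.16 (SE 0.13) and Aacs at -1.10 (SE 0.093). Cholesterol genes fell in 12 of 17 (14 adjusted over the list alone; mean -0.66, camera adjusted p = 4.64e-10), with Pmvk at -1.25 (SE 0.13), Lss at -1.14 (SE 0.13) and Fdps at -1.03 (SE 0.11). Glycolysis genes fell in 6 of 15 cases (6 fell and 1 rose adjusted over the list alone; mean -0.22, camera adjusted p = 0.00117). Among them were the insulin-responsive glucose transporter gene Slc2a4 (-1.05, SE 0.14), Aldoa (-0.58, SE 0.075) and Ldha (-0.52, SE 0.077). In the unfolded protein and integrated stress response list 3 of 21 genes rose (3 adjusted over the list alone; mean 0.30, camera adjusted p = 0.0262), among them Psat1 (0.78, SE 0.17). Its call was lost with the lymphocyte mean as a covariate (0.29, adjusted p = 0.0715), with array weights (0.27, adjusted p = 0.0527) and without normal diet replicate 3 (0.28, adjusted p = 0.0783), while its mean barely moved.

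MHC class II genes rose in 5 of 7 cases at week 24 (7 adjusted over the list alone; mean 0.69, camera adjusted p = 0.00154, adjusted p = 0.287 with an estimated correlation). Interferon genes rose in 6 of 20 (7 adjusted over the list alone; mean 0.40, camera adjusted p = 0.00134, adjusted p = 0.287 with an estimated correlation) and immediate early genes in 7 of 15 (8 adjusted over the list alone; mean 0.71, camera adjusted p = 0.00241, adjusted p = 0.30 with an estimated correlation). Lymphocyte markers averaged 8.54 ± 0.13 on high-fat and 8.08 ± 0.16 on normal diet (log2, SD, n = 3 each, camera adjusted p = 0.0908). With the lymphocyte mean as a covariate the MHC class II, interferon and immediate early lists no longer passed (adjusted p = 0.334, 0.247 and 0.23). Their means were then 0.24, 0.18 and 0.43. In the oxidative phosphorylation list 2 of 47 genes rose and 5 fell (1 and 4 adjusted over the list alone; mean -0.10, camera adjusted p = 0.0118, adjusted p = 0.30 with an estimated correlation). The imprinted growth network list averaged 0.34 with 3 of 8 risers, Peg3 (1.34, SE 0.20), Grb10 (0.46, SE 0.14) and Igf2r (0.26, SE 0.079) (3 adjusted over the list alone; camera adjusted p = 0.046, adjusted p = 0.0785 with an estimated correlation). That call was lost in 10 of 46 other settings, with a highest adjusted p of 0.101. The brown fat thermogenesis list had 3 risers and 3 fallers of 24 (3 and 3 adjusted over the list alone); its median was 0.05 and its mean 0.01, while the camera direction was down (adjusted p = 0.819). The skeletal muscle markers of the high-fat arrays spread by an SD of 1.35 around 9.67 at this week, against 0.21 around 9.72 on normal diet. In all, 1952 genes passed, 1217 higher and 735 lower, with 232 rising and 48 falling more than 2-fold. Leaving out normal diet replicate 1 gave 1259.

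**Figure D3:**
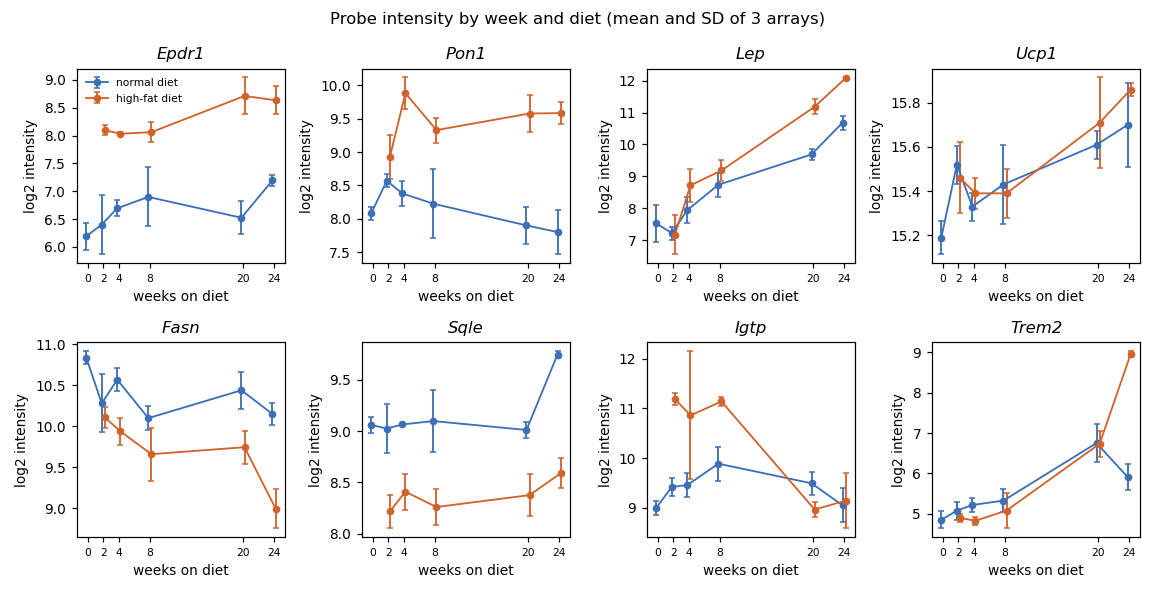
Log2 intensity of 8 genes against weeks on diet, as the mean and SD of 3 arrays per group, normal diet in blue and high-fat diet in orange. The vertical axes differ between genes. Epdr1 and Sqle passed at all 5 weeks, Pon1 at 4 and Lep at weeks 20 and 24, Igtp passed on high-fat diet at weeks 2 and 4 (1.77 and 1.40) and not later, and Trem2 separates the diets at week 24, where it stands at 8.96 on high-fat and 5.91 on normal diet.

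Whether the diet effect changed with time was tested as the mean effect at weeks 20 and 24 minus that at weeks 2 and 4. The effect was higher late for the macrophage genes Trem2 by 1.80 (SE 0.21, adjusted p = 2.15e-05), Gpnmb by 1.59 (SE 0.31, adjusted p = 0.00241) and Lgals3 by 1.4999 (SE 0.24, adjusted p = 3.9e-04). So it was for the carbonic anhydrase gene Car12 by 1.41 (SE 0.16, adjusted p = 1.89e-05) and the RNA-binding gene Samd4 by 1.23 (SE 0.20, adjusted p = 6.1e-04). Trem2 and Car12 were detected on 10 and 6 of the 33 arrays, so their values rest largely on signals below detection. The late minus early difference was negative for the interferon-induced genes Igtp (-1.80, SE 0.35, adjusted p = 0.00296), Irgm2 (-1.34, SE 0.25, adjusted p = 0.00204), Gbp10 (-1.28, SE 0.30, adjusted p = 0.0122) and Gbp2 (-1.27, SE 0.26, adjusted p = 0.00398). It was negative too for the lactate receptor gene Hcar1 (-1.26, SE 0.28, adjusted p = 0.00952). By list, the effect on extracellular matrix genes was higher late in 10 of 24 cases (18 adjusted over the list alone; mean 0.44, camera adjusted p = 2.53e-12), on macrophage genes in 7 of 23 (12 adjusted over the list alone; mean 0.53, camera adjusted p = 1.25e-08). It was also higher late on endothelial genes in 6 of 19 (12 adjusted over the list alone; mean 0.32, camera adjusted p = 2.21e-08) and on cell cycle genes in 6 of 19 (12 adjusted over the list alone; mean 0.50, camera adjusted p = 2.38e-08). It was lower late for 3 of 20 fatty acid synthesis genes (8 adjusted over the list alone; mean -0.25, camera adjusted p = 8.72e-07) and for 4 of 20 interferon genes (8 adjusted over the list alone; mean -0.39, camera adjusted p = 4.41e-05, adjusted p = 0.23 with an estimated correlation). The fatty acid synthesis list averaged 11.58, 11.57, 11.54 and 11.52 on high-fat diet at weeks 2, 4, 20 and 24. On normal diet it averaged 11.67, 11.84, 11.74 and 12.16, so the measured level stepped up at week 24 on normal diet and not on high-fat diet. The step to week 24 may hold a technical part on both diets, so these levels cannot say which diet moved. In all, 480 genes passed, 332 with a higher and 148 with a lower effect late. Without week 24 only 10 genes passed, Car12 and Irgm2 kept their calls (adjusted p = 0.0274 each), the cell cycle list (0.07) and the fatty acid synthesis list (-0.03) did not pass (adjusted p = 0.704 and 0.318), the macrophage list stood at -0.16 (adjusted p = 0.0674) and Gpnmb at -0.0077 (adjusted p = 0.997).

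A test of any change of the diet effect over the weeks was led by Slc37a2, a sugar-phosphate transporter gene of macrophages (adjusted p = 7.56e-11), followed by the actin-capping gene Capg (adjusted p = 2.76e-09), Ccl9 (adjusted p = 7.95e-09), Trem2 (adjusted p = 3.82e-08) and Arl11 (adjusted p = 1.3e-07). Slc37a2 averaged 7.44 ± 0.18 on high-fat and 5.05 ± 0.30 on normal diet at week 24 (log2, SD, n = 3 each) and was below detection in all groups except the former. Capg stood at 9.75 ± 0.091 on high-fat diet at week 24, with 7.57 ± 0.098 on normal diet. In all, 613 genes passed. Without week 24 the count was 1, and the named genes lost their calls (adjusted p = 0.285 to 0.996).

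On normal diet, the leptin gene Lep was higher at week 24 than at week 0 by 3.16 (SE 0.29, adjusted p = 1.77e-09), from 7.52 ± 0.57 to 10.7 ± 0.21 (log2, SD, n = 3 each), and stood 2.17 above week 0 at week 20. Nup210, a nuclear pore gene below detection at week 0, was at least 7.89-fold higher (adjusted p = 6.89e-14). Gldn rose by 2.97 (SE 0.22), the elastase gene Cela1 by 2.95 (SE 0.21) and the corneodesmosin gene Cdsn by 2.90 (SE 0.21). The muscle contractile genes Myl2 (3.57, SE 0.78), Tcap (2.73, SE 0.48) and Tpm2 (2.66, SE 0.47) and the muscle enzyme genes Pgam2 (2.66, SE 0.49) and Ckm (2.65, SE 0.51) rose beside the skeletal muscle list, of which 18 of 20 genes rose (18 adjusted over the list alone; mean 1.73, camera adjusted p = 4.95e-05, adjusted p = 0.634 with an estimated correlation). With the muscle mean as a covariate Myl2 was 0.75 (adjusted p = 0.144). Mup2, of the near-identical major urinary protein family, was below detection at week 24 and at least 17.4-fold lower than at week 0 (adjusted p = 1.29e-09), and the xenobiotic cytochrome gene Cyp2b10 changed by -4.39 (SE 0.43, adjusted p = 6.87e-09). Cyp2b23 and Pcmtd2 were below detection at week 24 and at least 4.05-fold and 4.45-fold lower. The lysolipid transporter gene Mfsd2a changed by -3.41 (SE 0.66), the glucocorticoid-induced genes Fkbp5 by -2.91 (SE 0.44) and Zbtb16 by -2.77 (SE 0.21), Rgma by -2.51 (SE 0.13), Ptges3 by -2.45 (SE 0.11) and Ddt by -2.45 (SE 0.13).

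Endothelial genes fell in 13 of 19 cases from week 0 to week 24 (13 adjusted over the list alone; mean -0.56, camera adjusted p = 4.95e-05, adjusted p = 0.115 with an estimated correlation). Among them were Esam (-1.19, SE 0.095) and Tek (-0.90, SE 0.11). Branched-chain amino acid breakdown genes fell in 11 of 18 cases and rose in 2 (11 and 3 adjusted over the list alone; mean -0.61, camera adjusted p = 3.66e-04, adjusted p = 0.0585 with an estimated correlation). Oxidative phosphorylation genes fell in 22 of 47 and rose in 5 (23 and 5 adjusted over the list alone; mean -0.33, camera adjusted p = 0.0053, adjusted p = 0.314 with an estimated correlation). Extracellular matrix genes fell in 11 of 24 cases and rose in 1 (12 and 1 adjusted over the list alone; mean -0.38, camera adjusted p = 0.0152, adjusted p = 0.314 with an estimated correlation). Glycolysis genes rose in 6 of 15 and fell in 1 (6 and 1 adjusted over the list alone; mean 0.30, camera adjusted p = 0.0233, adjusted p = 0.314 with an estimated correlation). In all, 4639 genes passed, 2312 higher and 2327 lower. At week 20 against week 0 the count was 3201, 1855 genes passed at both weeks in the same direction and 187 in opposite directions. There Pcmtd2 stood at 0.25 (adjusted p = 0.346), Ptges3 at -0.28 (adjusted p = 0.0541), Rgma at -0.80 and Ddt at -0.34. The amino acid, phosphorylation and glycolysis lists were near 0 (-0.05, 0.007 and -0.07, without a call), and the matrix list stood at -0.23 (adjusted p = 0.0524). Second probes moved the same way for 71.8% of the genes called at week 24 and for 85.4% of those called at week 20.

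A test of any change over the 6 normal diet weeks was led by Wdr73 (adjusted p = 2.09e-15), the branched-chain acyl-CoA dehydrogenase gene Acadsb (adjusted p = 1.59e-14), and Ptges3, Nup210 and Zc3h15 (adjusted p = 2.19e-14 each). Acadsb stood between 11.04 and 11.15 as a group mean from week 0 to week 20 and at 8.79 ± 0.25 (SD, n = 3) at week 24 (log2), whereas Nup210 stood at 5.86 ± 0.18 at week 0, 7.39 ± 0.11 at week 8 and 8.73 ± 0.22 at week 20 (log2, SD, n = 3 each). In all, 6400 genes passed. Without week 24 the count was 3503 and Acadsb, Ptges3 and Zc3h15 did not pass (adjusted p = 0.874, 0.0783 and 0.179).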

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

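The tests of a batch at week 24, of the macrophage share at weeks 2, 4 and 8, and of lipid-associated macrophages were chosen after the results had been seen. The fits without week 24 and the normalization test at week 2 were too. For weak RNA at week 8, and for normalization and unusual animals in the interferon pattern, the rules written beforehand would have excluded the explanation, and they were judged too weak after the results had been seen.

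A difference between late and early weeks drew attention to 480 genes whose diet effect differed at weeks 20 and 24 from that at weeks 2 and 4, and a difference between weeks to 613 genes with an interaction of diet and week. Among genes, the effect was higher late for Trem2 (1.7982, adjusted p = 2.15e-05), Gpnmb (1.5889, adjusted p = 0.00241), Lgals3 (1.4999, adjusted p = 3.9e-04), Car12 (1.4078, adjusted p = 1.89e-05) and Samd4 (1.2294, adjusted p = 6.1e-04). Trem2 and Car12 were below detection on most arrays (detected on 10 and 6 of 33). It was lower late for Igtp (-1.8001, adjusted p = 0.00296), Irgm2 (-1.3382, adjusted p = 0.00204), Gbp10 (-1.2824, adjusted p = 0.0122), Gbp2 (-1.2727, adjusted p = 0.00398) and Hcar1 (-1.2581, adjusted p = 0.00952).

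Among gene lists, the same difference between late and early weeks was positive for macrophages (0.5296), cell cycle (0.5021), extracellular matrix (0.4381), endothelial cells (0.3218) and the unfolded protein and integrated stress response (0.2158, adjusted p = 0.0108). It was negative for fatty acid synthesis (-0.2462). These 6 also passed with an estimated correlation (adjusted p = 0.0248, 5.42e-04, 0.00408, 0.0134, 0.0248 and 0.0328). Without week 24, 4 of these 6 did not pass, namely macrophages (-0.16, adjusted p = 0.0674), cell cycle (0.07, 0.704), the unfolded protein and integrated stress response (0.11, 0.275) and fatty acid synthesis (-0.03, 0.318). Another 7 passed only with the preset correlation. They were skeletal muscle (-0.7418, adjusted p = 0.441 with an estimated correlation), interferon response (-0.3888, 0.23), cholesterol synthesis and uptake (-0.1235, 0.303), fatty acid oxidation (-0.1127, 0.397) and oxidative phosphorylation (-0.1068, 0.23). The last were immediate early genes (0.4491, 0.465) and the imprinted growth network (0.2581, 0.109).

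A signal in data left out of the gene tests came from probes without exactly 1 gene symbol. Of 2467 such probes that were detected, 518 passed for the diet average, 220 higher and 298 lower. That is 21% of them, a smaller share than the 27.07% of the tested genes.

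The arrays of week 24 stood apart from those of all earlier weeks on both diets. The correlation between 2 probes of a gene was 0.353 lower for the normal diet change from week 20 to 24 than for that from week 0 to 20 (-0.353, 95% interval -0.40 to -0.308, over 3581 genes), which a probe-level hybridisation artefact would give. The brightest genes moved too (SD 2.01 times that of the step from week 8 to 20), which argues against a lower scanner background as the only cause. This ratio cannot exclude that the background played a part, since any other cause may have moved bright genes. The changes from week 20 to 24 correlated at 0.752 between the diets, and a batch and age cannot be told apart by it, since either would give this. These values would fit a technical part in the step to week 24. The diet difference of week 24, where 2 probes correlated at 0.703, was taken within that week. Its size against earlier weeks still depends on that step on each diet. At weeks 20 and 24 fatty acid synthesis genes averaged 11.74 and 12.16 on normal diet, and 11.54 and 11.52 on high-fat diet. Macrophage genes averaged 7.98 and 7.42 on normal diet, and 8.14 and 8.96 on high-fat diet.

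Of the genes that passed at week 8 alone, 15 of 20 with a second probe moved the same way on it (75%, 95% interval 50.9% to 91.3%), so a probe-level artefact and a real change cannot be told apart. The dimmest high-fat array deviated most in 15 of 74 genes (20.3%, 95% interval 11.8% to 31.2%) and replicate 1 in 41, the array with the lowest weight of all 33 (0.1187). All 3 high-fat arrays were dim, so weak RNA in the whole group and a real change cannot be told apart by this.

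Interferon response genes were higher on high-fat diet at weeks 2, 4 and 8 by the preset correlation, but not with an estimated correlation (adjusted p = 0.0785, 0.0579 and 0.157). They passed at week 24 too (0.40), by the preset correlation alone. At week 8 macrophage genes averaged -0.146 (SE 0.0484), which argues against a larger share of macrophages there. The high-fat arrays of that week were dim, so a change of cell share was not excluded. A larger share would fit weeks 2 and 4, where the smaller mean was 0.244 (SE 0.0793) and the other 0.388 (SE 0.122). Camera compares a list with all other genes and cannot judge a shift of all genes. Its highest adjusted p was 3.41e-07 over 3 settings, but the mean at week 8 was 0.436 and, with a median shift, 0.1343, so at week 8 the normalization and a real change of that size cannot be told apart. At week 2 the lowest mean over these settings was 0.436, against 0.559 (SE 0.0288) in the main fit, so these settings did not remove the rise. The spread between arrays was not taken in the other settings. All 9 of 9 high-fat arrays lay above every normal diet array of their week, but these weeks were picked for the rise. At week 4 the difference was 0.49 (SE 0.255) and 0.2547 without high-fat replicate 2, so a few unusual animals and a general rise cannot be told apart. An interferon response of the tissue itself might explain week 8, where macrophage genes stood at -0.146, and the cause was not tested further.

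Diet labels were also rearranged within weeks. For the diet average 1 of 100 splits, the real one with 2602 genes, gave as many genes, and the highest other gave 196. For the late against early test 2 of 100 did (480 real, 863 highest other), and the other split kept the week 24 groups. For the interaction 6 of 100 did (613 real, 1197 highest other), so chance was not excluded by this count. All 5 others kept the week 24 groups, and splits that did not gave at most 4 genes. For change over the normal diet weeks 1 of 100 did (6400 real, 766 highest other). Within single weeks the splits are too few for a share under 0.05. The real split was the 1 with the most genes at week 2 (183, highest other 0), week 4 (115, 0), week 8 (202, 12), week 20 (449, 1) and week 24 (1952, 0), and for week 24 against week 0 on normal diet (4639, 19).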

How the results depend on the processing

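The settings without week 8, without week 24 and with week 20 in place of week 24 were chosen after the results had been seen. Where no cause is named, the cause was not tested.

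No background correction gave 197 genes at week 4, the authors' values 180, and a trended robust prior 183. A median shift gave 90 genes at week 2, 62 at week 4, 3727 at week 8, 252 for late against early, 1815 for the interaction and 11 lists at week 20. It reversed the diet averages of Ucp1 (-0.1223), Adipoq (-0.05282) and Lpl (-0.09393) and the citric acid cycle list at week 8 (-0.2723). No detection filter gave 119 genes at week 2 and 17 lists for the diet average, and the mean of a gene's probes 10 lists at week 20. Array weights gave 572, 495, 405 and 2972 genes at weeks 2, 4, 8 and 24, 1068 for late against early and 1727 for the interaction. The skeletal muscle covariate gave 90 genes at week 2. The 6 arrays of 1 week alone, with fewer arrays to estimate variance, gave 64, 1, 1 and 35 genes at weeks 2, 4, 8 and 20. In that setting 23 of 50 named gene results lost their calls and 0 reversed.

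An estimated correlation left 7 lists for the diet average, 0, 4, 1, 1 and 9 at weeks 2, 4, 8, 20 and 24, 6 for late against early and 0 for week 24 against week 0. Without week 8 there were 286, 204 and 744 genes at weeks 2, 4 and 20. Without week 24 there were 1470 genes for the diet average, 128 at week 8, 10 genes and 7 lists for late against early, 1 for the interaction and 3503 over the normal diet weeks. This reversed the late against early values of Gpnmb (-0.007677), the cholesterol synthesis and uptake list (0.1169) and the macrophages list (-0.1596). Week 20 in place of week 24 reversed Pcmtd2 (0.2487), the oxidative phosphorylation list (0.006999) and the glycolysis list (-0.06647) on normal diet.

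A replicate block gave 2559 genes for the diet average, 161, 106, 179, 410 and 1896 at weeks 2, 4, 8, 20 and 24, 425 for late against early, 578 for the interaction, 4584 for week 24 against week 0 and 6290 over the normal diet weeks. Only 12 of 33 arrays were closest to arrays of their own number, so no pairing by number was seen. A weak pairing is not excluded by this. A BeadChip block was not run because the chip of each array is not given.

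Leaving out 1 array at a time gave 2426 to 2892 genes for the diet average, 68 to 322 at week 2, 53 to 247 at week 4, 51 to 491 at week 8, 190 to 764 at week 20 and 1259 to 2405 at week 24. It gave 332 to 719 for late against early, 367 to 866 for the interaction, 3856 to 5035 for week 24 against week 0 and 5890 to 7062 over the normal diet weeks. Counts moved more than 1.5-fold at week 2 without any of its 6 arrays (68 to 109) or high-fat week 8 replicate 1 (322). They did at week 4 without normal diet replicates 2 or 3 (54, 53), high-fat replicate 2 (57) or high-fat week 8 replicate 1 (247). At week 8 they did without normal diet replicates 1, 2 or 3 (51, 118, 54) or high-fat replicates 2 (491) or 3, and at week 20 without normal diet replicates 1 (190), 2 or 3, high-fat replicate 3 (237) or high-fat week 8 replicate 1 (764). Lists numbered 11 to 14 for the diet average, 7 to 10, 7 to 11, 6 to 7, 5 to 8 and 12 to 16 at weeks 2, 4, 8, 20 and 24, 9 to 13 for late against early and 5 to 6 for week 24 against week 0, with 8 at week 20 without normal diet or high-fat replicate 3 of that week. At week 24 normal diet replicate 1 mattered (1259), and for the interaction it (367) and high-fat replicates 1 and 2. Named genes reversed in 0 of 4026 such results. Signal over background limited the genes tested to 9613 of 19057.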

Other observations

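The tests of lipid-associated macrophages were chosen after the results had been seen. The glucocorticoid test was prompted by 3 genes already seen, and its prediction was written before the other genes were examined.

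On high-fat diet the mitochondrial isocitrate dehydrogenase gene Idh2 rose by 0.54 on average while the cytosolic malate dehydrogenase gene Mdh1 changed by -0.39. The clock genes Per1 and Per2 changed by -0.48 and -0.47, and their list did not pass (adjusted p = 0.0837). At week 24 resident macrophage genes rose, among them Folr2 (1.49, SE 0.162), Pf4 (1.43, SE 0.297) and Mrc1 (1.30, SE 0.141), whereas the lipid chaperone gene Fabp5 changed by -0.93 (SE 0.219).

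At week 2 the glucocorticoid-induced genes Fkbp5 (-1.84, adjusted p = 0.0267), Zbtb16 (-0.93, adjusted p = 0.0191) and Per1 (-0.92, adjusted p = 0.0493) were lower on high-fat diet. The call of Fkbp5 was lost in 7 of 47 other settings, among them the skeletal muscle covariate, and muscle markers averaged 0.97 higher at that week. Lower glucocorticoid action could give this, and it predicts that other induced genes fall. Of 23 others 18 were lower, with a mean of -0.233 (camera p = 0.000727, and 0.0697 with an estimated correlation), and 1 passed, Sult1a1 at -0.572. At weeks 4, 8 and 20 the means were 0.005, -0.007 and 0.014. At week 24 the list went the other way, with 18 higher and a mean of 0.27 (camera p = 0.0399, and 0.259 with an estimated correlation). From week 0 to week 24 on normal diet 15 of the 23 fell past the threshold and 2 rose. The mean there was -0.603 (camera p = 0.000103, and 0.0393 with an estimated correlation), so these genes also changed with time without the high-fat diet. These p-values were not adjusted over the comparisons. The week 2 values would fit lower glucocorticoid action by the preset correlation only, and hormone was not measured.

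Macrophages at week 24 might have taken on a lipid-associated state. The score of 7 lipid-associated genes rose more than that of 8 resident genes, by 0.398 (SE 0.088), but 3 of the 7 had been seen before, so the state and the selection of those genes cannot be told apart. Without Gpnmb, Trem2 and Lgals3 the difference was -0.824 (SE 0.0757), the opposite of the prediction. These 3 rose most of the 7, so leaving them out lowers the score whatever the state. The 4 left were Cd9 (0.87), Lipa (0.63), Ctsl (0.30) and Fabp5 (-0.93). Neither score can therefore decide whether macrophages took on this state.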
